A study of Homo sapiens with 6 samples.

How the data were processed

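RNA sequencing values of 6 samples of LX-2, an established human hepatic stellate cell line, were analysed: 3 control samples and 3 samples given transforming growth factor beta 1 (TGF-β1). Poly-A or other RNA selection is not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit, which does not mark strand. The submitters' processing notes name HISAT2, HTSeq version 0.13.5 and the genome build GRCh38, with no role or order, and the annotation release is not given in the sources used here.

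The deposited table held 27830 genes, each with a whole-number read count per sample and an FPKM value per sample. Per the file headers, the first 6 value columns are counts, deposited without normalization. The FPKM values deposited by the authors followed from the counts: the gene length needed to turn one into the other was the same whole number in all 6 libraries for each gene, with the total of the table as denominator. The table gave neither biotype nor coordinates nor any mark of transcription factors. Ensembl identifiers were matched to GENCODE release 29 on GRCh38, which covered 26980 genes and left 850 unmatched. Coordinates, transcript GC content and overlap with other genes come from that annotation. For 6866 genes the table repeated the identifier in place of a symbol.

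Counts were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood F test with robust fitting, TMM normalization and the filterByExpr filter. The filter kept 14463 genes. P-values were adjusted by the Benjamini-Hochberg method over these genes, with calls at an adjusted p under 0.05. Calls with an absolute log2 fold change of at least 1 were also counted. Levels are CPM, read counts scaled by library size, on TMM-scaled library sizes (total counts for summed markers), as mean ± SD of 3 libraries, and log2 fold changes carry their standard error (SE). The 27 gene lists were fixed before the data were examined, and 26 had the 5 tested members that the list test required. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, two-sided, with adjustment over 26 lists. Shares of counts and summed marker levels were compared by an exact permutation test, two-sided, whose smallest possible p with 3 against 3 samples is 0.1.

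Genes named in the text followed a rule fixed before the data were examined. It took a panel of 13 genes whatever their result, up to 4 called members per list with the largest absolute log2 fold change, and the 10 largest increases and 10 largest decreases. The last part was limited to called genes with a symbol, a mean of at least 5 CPM and groups that did not overlap. The rule named 40 genes in all, and some of them are not reported here. Other genes are named where a count would otherwise be opaque, and were then chosen after their values were seen.

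On simulated counts for 14463 genes of the TGF-β1 comparison, the edgeR test recovered 13.4% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 90.9% of those changed 4-fold, with 4.17% false calls. When the dependence on GC content seen in the libraries was simulated too, 1.5-fold changes were recovered in 16.4% without and 55.2% with removal of that trend. False calls were then 5.97% and 6.43%. The simulated trend was the one that the removal fits, so the gain was partly fixed in advance. DESeq2 had 12.5% false calls on counts simulated without the trend. Counts were drawn for each gene independently with dispersions estimated by edgeR, so the comparison with DESeq2 may favour edgeR. Library totals ran from 13866957 to 17694675 counts. A count of 3, taken as the detection floor, corresponded to 0.17 to 0.216 CPM, which covers counting error only.

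Alternatives set before the data were examined were other scaling factors, no filter and a stricter one of 1 CPM in 3 samples, the replicate number as a block, each sample left out in turn, DESeq2 1.42.0, limma voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and for lists an estimated correlation and fry. Chosen after seeing the data were the removal of a smooth trend of each library on transcript GC content (loess, span 0.5), the same with gene length, that removal with the block, and a restriction to protein-coding genes of GENCODE.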

Results

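The response of LX-2 cells to TGF-β1, the main profibrotic cytokine of the liver, was measured by RNA sequencing in 3 control samples and 3 samples given 10 ng/ml for 24 h. Total counts were 14118402, 17694675 and 16336221 in control replicates 1 to 3, and 16282815, 16454700 and 13866957 in TGF-β1 replicates 1 to 3. The labels place the TGF-β1 treatment in serum-free medium and do not give the medium of the controls, so a difference in serum may be part of every difference between the groups given here. Nor do they say that the 3 samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical. Within each group the libraries differed by more than counting noise, with chi-square values of 5.21 to 45.7 per degree of freedom, and no pair was treated as a duplicate.

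The first question was which genes differ after TGF-β1. FN1, which encodes fibronectin, rose 3.61-fold, from 985 ± 68.9 to 3558 ± 184 CPM (SD, n = 3 per group; edgeR adjusted p = 5.11e-05). TGFBI, a secreted matrix protein, rose 3.35-fold from 952 ± 51.6 to 3190 ± 305 CPM (edgeR adjusted p = 7.7e-05). TAGLN, the actin-binding smooth muscle protein transgelin, rose 3.11-fold from 97.7 ± 4.13 to 304 ± 53.2 CPM (edgeR adjusted p = 0.000682). CPA4, a carboxypeptidase, showed the largest decrease of the named genes, 2.79-fold, from 60.3 ± 3.85 to 21.6 ± 3.11 CPM (edgeR adjusted p = 0.0024). In all, 27 genes rose and 26 fell among 14463 tested by edgeR, and 18 and 10 of these changed by at least 1 on the log2 scale. At an unadjusted p under 0.05, 2262 genes passed. Without TGF-β1 replicate 2 the number of calls was 4 (FN1, TGFBI, TAGLN and LRRC15 among the named genes), and without TGF-β1 replicate 3 it was 1671. It was 324 without TGF-β1 replicate 1, and 13 and 15 without control replicates 1 and 3.

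**Figure D1:**
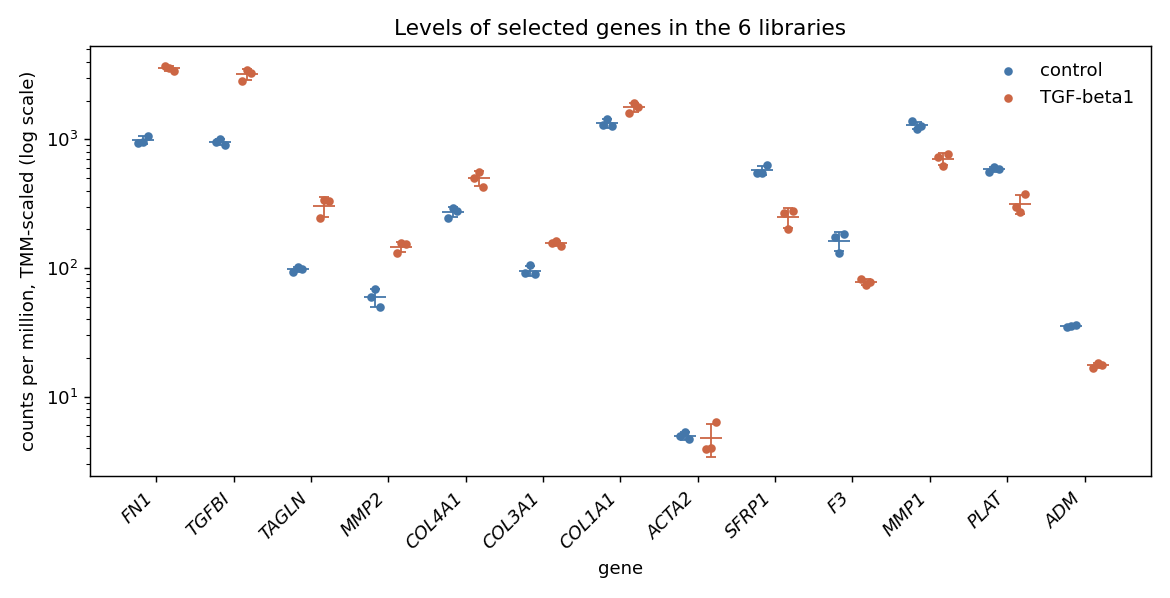
CPM on TMM-scaled libraries (log axis) of 13 genes in 3 control and 3 TGF-β1 libraries; points are libraries, horizontal marks are means and bars are SD. FN1, TGFBI and TAGLN were higher in each TGF-β1 library than in each control library, while ACTA2 overlapped, with means of 5.002 and 4.77 CPM.

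Genes of the extracellular matrix were tested as fixed lists. Among the 36 tested non-collagen matrix proteins, 7 rose and 1 fell. VCAN, the proteoglycan versican, rose 3.78-fold from 21.3 ± 3.37 to 80.8 ± 29.6 CPM (edgeR adjusted p = 0.00726), and LTBP2, a latent TGF-β binding protein family member, rose 2.55-fold (edgeR adjusted p = 0.00289). The other increases included TNC and FBLN5, and the decrease was in the laminin chain gene LAMA5. In this list 9 members rose and 4 fell when adjusted over the list alone. The list as a whole did not pass camera (adjusted p = 0.1, and 0.00193 to 0.309 with 1 library left out). With the GC trend removed it did (adjusted p = 0.00765), but not with an estimated correlation as well (adjusted p = 0.548).

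Among 23 collagen chains, 3 rose and 1 fell. COL4A1, a basement membrane collagen, rose 1.83-fold from 271 ± 24.0 to 498 ± 65.3 CPM (edgeR adjusted p = 0.0202), COL5A1 rose 1.65-fold (edgeR adjusted p = 0.0418) and COL3A1 rose 1.64-fold (edgeR adjusted p = 0.035). COL4A6 was 1.97-fold lower (edgeR adjusted p = 0.0397). COL1A1, the main fibrillar collagen, had 1331 ± 99.7 and 1770 ± 155 CPM, a log2 difference of 0.41 ± 0.12 (SE) that did not pass (edgeR adjusted p = 0.159). It passed with the GC trend removed (log2 difference 0.53, edgeR adjusted p = 0.00739). COL1A2 had 29 to 48 counts per library and did not pass (edgeR adjusted p = 0.487). Of the chains 7 rose and 4 fell when adjusted over the list alone. Camera gave adjusted p = 0.159 for the chains (0.0417 to 0.513 with 1 library left out), and 0.00989 with the GC trend removed (adjusted p = 0.548 with an estimated correlation too). None of the 25 collagen processing and cross-linking genes was called (camera adjusted p = 0.951), and none passed when adjusted over the list alone. With the GC trend removed, SERPINH1 (edgeR adjusted p = 0.00999) and PLOD2 (0.0427) rose and LOX fell (0.0181).

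Of 32 matrix proteases and inhibitors, 2 rose and 2 fell. MMP2, gelatinase A, rose 2.47-fold from 59.3 ± 9.37 to 146 ± 14.1 CPM (edgeR adjusted p = 0.00309). MMP13, a collagenase, rose 6.95-fold from a low level of 0.316 ± 0.0623 to 2.22 ± 0.609 CPM (edgeR adjusted p = 0.0126). MMP1, interstitial collagenase, was 1.82-fold lower, at 1285 ± 85.6 and 707 ± 73.5 CPM (edgeR adjusted p = 0.0139), and PLAT, tissue plasminogen activator, was 1.84-fold lower (edgeR adjusted p = 0.0225). TIMP1, a metalloproteinase inhibitor, had 550 ± 49.0 and 613 ± 98.9 CPM (edgeR adjusted p = 0.631). Adjusted over the list alone, 7 rose and 3 fell. Camera gave adjusted p = 0.653.

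Among 27 contractile and cytoskeletal genes, TAGLN and TPM1 rose. TPM1, a tropomyosin, rose 1.79-fold from 346 ± 4.93 to 619 ± 113 CPM (edgeR adjusted p = 0.0314), and 21.4% of its exon bases overlap other genes. ACTA2, which encodes α-smooth muscle actin, was low in both groups, with 70, 92 and 77 counts in the controls and 65, 68 and 86 with TGF-β1. Its log2 difference was -0.08 ± 0.24 (SE), with a 95% interval of -0.60 to 0.44 (edgeR adjusted p = 0.898). ACTA2 lies on chromosome 10 from 88935074 to 88991339 of GRCh38, on the minus strand, and 30.1% of its exon bases overlap exons of other genes, ACTA2-AS1 and FAS on the opposite strand among them, so its counts are uncertain without strand. VIM had 1418 ± 47.8 and 1227 ± 117 CPM (edgeR adjusted p = 0.423), and 24.4% of its exon bases overlap other genes. DES had 1 to 5 counts per library and was not tested. In this list 4 members rose adjusted over the list alone. Camera gave adjusted p = 0.757.

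Of 41 TGF-β pathway and feedback genes, PMEPA1, a feedback inhibitor of the pathway, rose 2.42-fold from 20.3 ± 3.09 to 49.1 ± 13.96 CPM (edgeR adjusted p = 0.0314). SMAD7, another feedback inhibitor, had 20.9 ± 1.42 and 27.9 ± 4.72 CPM (edgeR adjusted p = 0.268). CCN2, connective tissue growth factor, is not in this list but among the non-collagen matrix proteins and the YAP and TEAD targets. CCN2 had 159 ± 14.6 and 150 ± 11.7 CPM (edgeR adjusted p = 0.778). Pathway members adjusted over the list alone included 5 that rose and 2 that fell. Camera gave adjusted p = 0.951.

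Genes outside the matrix lists with large increases were LRRC15, a membrane protein of activated fibroblasts (3.77-fold, 10.7 ± 1.77 to 40.4 ± 3.67 CPM, edgeR adjusted p = 0.000751), SPOCK1, a proteoglycan (3.09-fold, edgeR adjusted p = 0.00477), and SCG5 (2.99-fold, edgeR adjusted p = 0.00599). The decreases included SEMA3B, a semaphorin (2.72-fold, edgeR adjusted p = 0.00261), DMBT1 (2.72-fold, edgeR adjusted p = 0.035) and TNFRSF1B, a receptor of tumour necrosis factor (2.24-fold, edgeR adjusted p = 0.0172). FN1 lies on chromosome 2 from 215360440 to 215436172, TGFBI on chromosome 5 from 136028895 to 136063818, and TAGLN on chromosome 11 from 117199321 to 117204782 of GRCh38. No exon base of FN1 or TGFBI overlaps another gene, against 11.4% for TAGLN.

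The second question was which gene lists moved as a group. Glycolysis and hypoxia genes were lower (median log2 difference -0.25 over 30 members, camera adjusted p = 8.37e-06), with ADM, adrenomedullin, called at 2.02-fold lower (35.5 ± 0.539 to 17.6 ± 0.795 CPM, edgeR adjusted p = 0.0139). YAP and TEAD targets were lower (25 members, camera adjusted p = 0.0336), with F3, tissue factor, 2.09-fold lower (edgeR adjusted p = 0.0113), IGFBP3 2.52-fold lower (edgeR adjusted p = 0.0418) and AJUBA 1.63-fold lower (edgeR adjusted p = 0.0382). NRF2 and oxidant defence genes were lower (30 members, camera adjusted p = 0.0452), with NQO1 1.66-fold lower (edgeR adjusted p = 0.0449). Of the exon bases of NQO1, 17.7% overlap other genes. Stellate cell quiescence genes (21 members, camera adjusted p = 0.0452) and macrophage and leukocyte markers (6 members, camera adjusted p = 0.046) were lower, and cholesterol synthesis (25 members, camera adjusted p = 0.0452) and endoplasmic reticulum chaperones (28 members, camera adjusted p = 0.0495) were higher, with no member called. None of the 7 lists passed with an estimated correlation: adjusted p = 0.502 in 6 lists and 0.655 for the quiescence genes. With the GC trend removed, the glycolysis (adjusted p = 0.000328), cholesterol (0.00482) and NRF2 lists (0.0129) passed camera, and the YAP and TEAD (0.055), quiescence (0.106), chaperone (0.0749) and leukocyte lists (0.113) did not; with an estimated correlation as well, the first 3 lists had adjusted p = 0.548. With 1 library left out, the glycolysis list passed each time (adjusted p up to 0.0005) and the leukocyte list never did (0.0638 to 0.230). The YAP and TEAD list missed the threshold without control replicate 3 (0.175) or TGF-β1 replicate 3 (0.132), and the NRF2 list without control replicates 2 or 3 (up to 0.0535). The quiescence list passed only without TGF-β1 replicates 2 (0.0339) or 3 (0.0495), against up to 0.128 without the others. The cholesterol list passed only without control replicate 2 (0.011) or TGF-β1 replicate 1 (0.000496), against up to 0.241, and the chaperone list only without TGF-β1 replicate 1 (0.0417), against up to 0.192. Adjusted over the list alone, 1 glycolysis gene fell, 3 YAP and TEAD targets rose and 6 fell, 1 NRF2 gene fell, 1 quiescence gene rose and 1 fell, 2 leukocyte markers fell, 1 cholesterol gene rose and 0 chaperones changed.

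**Figure D2:**
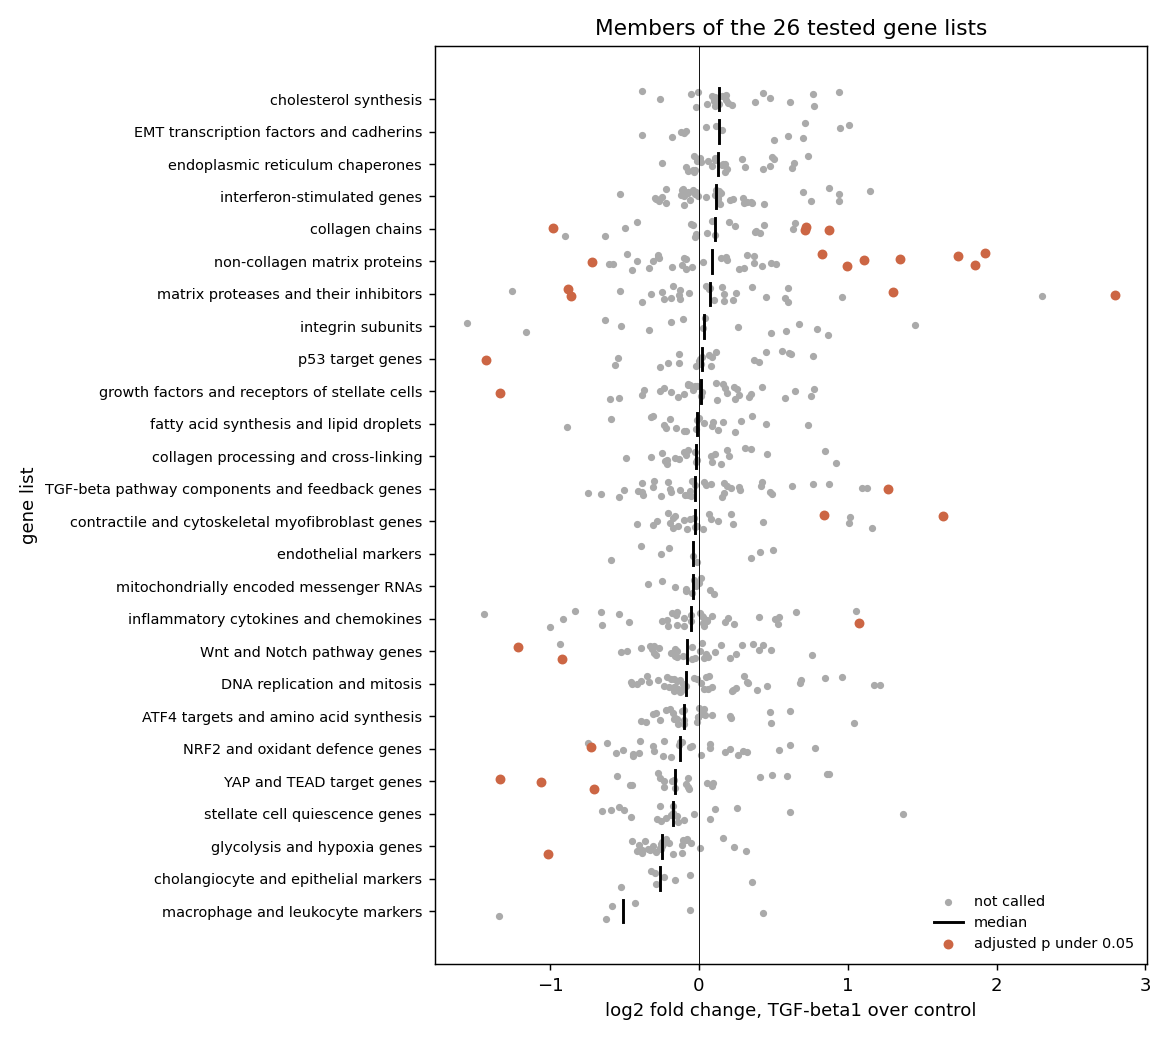
Log2 fold change (TGF-β1 over control, x axis) of each tested member of the 26 gene lists (y axis), with the median as a black bar and members with edgeR adjusted p under 0.05 in orange. The median was lowest for macrophage and leukocyte markers, at -0.51, and glycolysis and hypoxia genes had a median of -0.25.

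Other lists did not pass camera. Of 36 Wnt and Notch genes, the secreted Wnt inhibitors SFRP1 (2.32-fold, 576 ± 47.1 to 248 ± 42.0 CPM, edgeR adjusted p = 0.00427) and DKK1 (1.89-fold, edgeR adjusted p = 0.0118) fell, and the list had camera adjusted p = 0.1 (0.0495 to 0.230 with 1 library left out). Of 37 inflammatory genes, the chemokine gene CXCL12 rose 2.10-fold (edgeR adjusted p = 0.0279), and camera gave adjusted p = 0.316. GDF15 fell 2.70-fold among 23 p53 targets (edgeR adjusted p = 0.0314; camera adjusted p = 0.897), and IGFBP3 was the only call among 34 growth factors and receptors (camera adjusted p = 0.951). No member was called among integrin subunits (camera adjusted p = 0.918), EMT factors and cadherins (0.194), interferon-stimulated genes (0.757), DNA replication and mitosis (0.507), fatty acid synthesis (0.653) and ATF4 targets (0.217). Adjusted over the list alone, 2 Wnt genes fell, 3 inflammatory genes rose and 3 fell, 2 p53 targets fell, 1 growth factor gene fell, 4 integrins rose and 5 fell, 5 EMT genes rose and 1 fell, 1 mitosis gene rose and 2 fatty acid genes fell. Median and mean differed in sign for the contractile, collagen processing, TGF-β pathway and mitosis lists, and the direction of camera went against both for the growth factor, integrin and p53 lists.

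Levels of markers of other cell types were compared as sums of CPM on total counts. Summed hepatocyte markers were 58.8 ± 1.67 and 71.5 ± 6.33 CPM (exact permutation p = 0.1, the smallest possible), and leukocyte markers 38.0 ± 4.16 and 30.1 ± 1.79 CPM (exact permutation p = 0.1). A few genes carried most of these differences: CPS1 had 25.4 and 37.2 CPM among the hepatocyte markers, and CD14 had 15.6 and 10.3 CPM and ITGAX 12.9 and 9.69 CPM among the leukocyte markers. Epithelial markers were 689 ± 57.0 and 611 ± 90.4 CPM (exact permutation p = 0.4) and endothelial markers 502 ± 9.72 and 499 ± 3.52 CPM (exact permutation p = 0.8). KRT8 (376 and 341 CPM) and KRT18 (220 and 182 CPM) made up most of the epithelial sum, with EPCAM at 0.0424 and 0.0205 CPM. TIE1 (326 and 287 CPM) and FLT1 (116 and 149 CPM) made up most of the endothelial sum, with PECAM1 at 2.58 and 2.21 CPM. No marker of these lists was called, and camera gave adjusted p = 0.1 for epithelial and 0.951 for endothelial markers; 3 hepatocyte markers were too few for camera. Adjusted over the list alone, 1 hepatocyte marker (CPS1) rose and no epithelial or endothelial marker passed. Mitochondrially encoded messenger RNAs took 1.82% ± 0.0961 and 1.79% ± 0.0831 of counts (exact permutation p = 0.5), and camera gave adjusted p = 0.217 over 12 members, and 0.044 with the GC trend removed (0.652 with an estimated correlation too). Ribosomal protein genes took 4.26% ± 0.298 and 3.91% ± 0.531 (exact permutation p = 0.4), histone genes 0.0303% ± 0.000139 and 0.0292% ± 0.00244 (exact permutation p = 0.9) and the top 10 genes 5.09% ± 0.121 and 4.65% ± 0.398 (exact permutation p = 0.1).

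The libraries differed in how levels followed GC content. Medians of the log2 deviation from the gene mean were taken over 234 genes with a transcript GC content up to 35%. They were 0.68, 0.24 and -0.18 in TGF-β1 replicates 1 to 3, and -0.08, -0.42 and -0.15 in control replicates 1 to 3. The trend was thus partly aligned with the groups, and log2 differences of the first test carry part of it. Its removal took that of FN1 from 1.85 to 1.66 and that of TAGLN from 1.64 to 1.75. With this trend removed, 239 genes rose and 212 fell, and all 53 calls of the first test were among these 451 with the same sign. The count ranged from 69 without TGF-β1 replicate 2 to 1386 without TGF-β1 replicate 3, with 87 and 143 without control replicates 1 and 2.

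**Figure D3:**
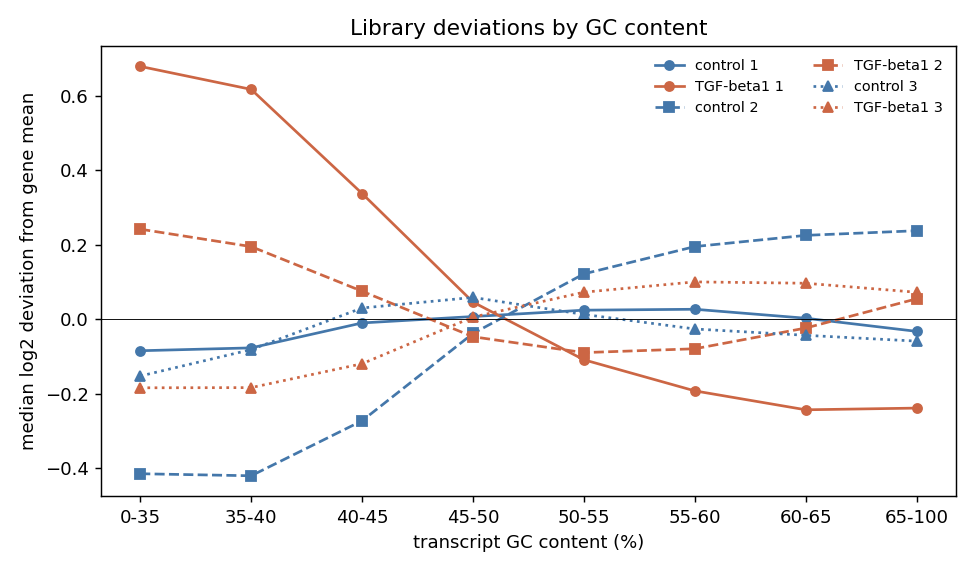
Median log2 deviation from the gene mean (y axis) in each of the 6 libraries, by transcript GC content in percent (x axis). At a GC content up to 35%, TGF-β1 replicate 1 was at 0.68 and control replicate 2 at -0.42.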

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

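Removal of the GC trend, of the GC and length trend, GC removal with the block and the protein-coding restriction were chosen after seeing the data. Of the 53 calls (27 higher, 26 lower, 28 of at least 1 on the log2 scale), counts stayed within 1.5 times under DESeq2-type size factors, total counts only, the stricter filter, protein-coding genes, limma voom and FPKM, except for 18 large changes with log2(FPKM + 1). Upper quartile factors gave 111 calls (57 higher, 54 lower, 73 large), no filter 1240 (1071, 169, 331) and DESeq2 590 (457, 133, 198). The GC trend removed gave 451 (239, 212, 76) and GC with length 555 (306, 249, 70). Leaving out 1 sample gave 4 to 1671 calls, 4 to 1374 higher, 0 to 297 lower and 4 to 664 large, with 13 calls without control replicate 1, 15 without control replicate 3 and 324 without TGF-β1 replicate 1. With the GC trend removed, leaving out 1 sample gave 69 to 1386 calls. Lists called numbered 7, against 2 with upper quartile factors, 0 with an estimated correlation, 0 with directional fry, 11 with mixed fry and 1 to 8 without 1 sample. Mixed fry, which takes changes in either direction, passed 4 of the 7. Among the lists it passed and camera did not were non-collagen matrix proteins (mixed fry adjusted p = 3.08e-05) and matrix proteases (0.0006). Contractile genes (0.000949) and collagen chains (0.00156) were others. Apart from the calls without TGF-β1 replicate 3, weighed below, the causes were not tested.

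The replicate number as a block gave 527 calls (429 higher, 98 lower, 202 large) and 4 lists, and with the GC trend removed 229 calls (113 higher, 116 lower, 50 large). Deviations of same-numbered samples correlated at 0.176, 0.1 and -0.355, and not every sample correlated best with its own number. These correlations were taken with the GC trend left in, so they do not decide whether the numbers pair the samples.

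No called list reversed, and no called gene among those of the naming rule did. For other called genes, direction was not checked in settings where they lost the call. Among results not called, ACTA2 was at 0.00645 with GC and length removed and at -0.328 to 0.0349 without 1 sample. The lists below took the opposite direction in at least 1 alternative, given as adjusted p, with the range without 1 sample. Collagen processing had 0.992 (upper quartile), 0.905 (no filter), 0.982 (block) and 0.254 to 0.973, and the TGF-β pathway 0.919 (FPKM) and 0.646 to 0.973. Growth factors had 0.909 (stricter filter), 0.797 (fry), 0.942 (FPKM) and 0.815 to 0.947, and integrins 0.917 (block), 0.935 (GC removed) and 0.789 to 0.973. Fatty acid synthesis had 0.676 (GC removed), endothelial markers 0.909 (stricter filter), 0.797 (fry), 0.592 (GC removed) and 0.751 to 0.973, and contractile genes 0.166 to 0.973.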

Other observations

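The tests of GC content, gene length, the response along the first component, control RNA in replicate 3, and the depth and overlap of ACTA2 were chosen only after the results were seen. Several called genes outside the naming rule were picked after their values were seen. MYCT1 rose by a log2 difference of 2.32 (edgeR adjusted p = 0.00386). PODXL, the sialomucin podocalyxin, was higher by 0.72 (edgeR adjusted p = 0.0314). C3, the central complement component, was at -0.94 (edgeR adjusted p = 0.0314) and PTX3, a pentraxin, at -0.76 (edgeR adjusted p = 0.035). DUSP1, a MAP kinase phosphatase, was at -0.72 (edgeR adjusted p = 0.035), and ADARB1, an RNA editing enzyme, at -0.90 (edgeR adjusted p = 0.0139).

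With the GC trend removed, an alternative chosen after seeing the data, 1 of 16 integrin genes rose and 1 fell. ITGAV, whose product binds and activates latent TGF-β, was higher by 1.002 (edgeR adjusted p = 0.00118), and ITGA7 was at -0.41 (edgeR adjusted p = 0.0201). VCAM1 was at -1.30 (edgeR adjusted p = 0.00206) and PTGS2, cyclooxygenase 2, at -1.005 (edgeR adjusted p = 0.00739) in the same fit, while CDH2, N-cadherin, was at 0.53 (edgeR adjusted p = 0.00697).

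The first principal component, 56.3% of the variance, did not follow the groups: TGF-β1 replicate 3 scored -10.2, inside the control range of -37.9 to -6.59. A difference in depth is argued against, since thinning all libraries to the smallest total hardly moved the scores (r = 0.9999). The loadings followed transcript GC content across genes (rho = -0.692; genes are not independent replicates), so a GC bias between libraries is a candidate explanation. With the GC trend removed, 0 of the 3 TGF-β1 libraries scored inside the control range on the first component (42.1% of the variance): controls had -20.3, -23.8 and -9.42, and TGF-β1 libraries 33.1, 18.1 and 2.29. A response to TGF-β1 beneath the GC trend may therefore be part of it, although 1 of the 10 splits of the 6 samples would separate as fully on any component. Gene length stays open, with a mean absolute rho of 0.176 within GC deciles, between the bounds set for it.

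Without TGF-β1 replicate 3 the calls rose from 53 to 1671. The ratio of the counts was still 31.5 after thinning, which argues against depth. It was 3.07 with the GC trend removed, which argues against the fitted GC trend as the whole cause. A GC effect that the fit did not capture is not covered by that ratio. Over the 116 tested matrix-list genes, called or not, each TGF-β1 library's log2 deviations from the control mean were set against the mean of the remaining TGF-β1 libraries. In these deviations the GC trend, already removed by the fit, was subtracted again. The slope was 0.974, 1.04 and 0.688 in replicates 1 to 3, and replicate 3 lay 0.287 under the lower of the others (difference -0.287, 95% bootstrap interval of genes -0.457 to -0.0766). Genes are not independent replicates, and the libraries were kept fixed, so the interval does not measure the spread between libraries. The repeated subtraction overcorrects for GC content by amounts that differ between libraries, so the slopes do not decide whether replicate 3 responded less. Control RNA in that library and a weaker response of that sample stay open, and the test does not tell them from each other.

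ACTA2 did not pass the test, although the series design text names its product as the marker of activation, measured there by other assays not analysed here. Too few reads to show a doubling is argued against by the upper 95% bound of 0.44 on the log2 scale. Of its 2972 words of 100 bases, 0% occur in another gene, which argues against a loss of most reads to other actin genes. Exons of other genes on either strand overlap 30.1% of its exon bases, merged over all its transcripts. Where its reads lie was not examined, so this share does not decide how many reads the overlap hides, and that loss stays open. The difference in serum between growth and treatment medium stays open as an untested explanation.

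The 6 samples can be split in 10 ways, too few for a share under 0.05. The real split gave 53 genes, 451 with the GC trend removed and 7 lists, and in each case 1 split, the real one, reached that number. The highest of the others was 0 genes, 0 genes with the GC trend removed and 3 lists. Each of the others puts control and TGF-β1 samples in both groups, so a response would add to the spread within groups and lower the number of genes. Of these, only the split of control replicates 1 and 3 with TGF-β1 replicate 2 called no list.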
